A study of Mus musculus with 21 samples.

How the data were processed

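RNA was measured in 21 samples on single-colour Illumina bead arrays carrying 45281 probes. There were 7 groups of 3 samples, namely EpiLC and PGCLC of WT, Otx2-null and Otx2/Blimp1-null lines, and sorted cells of Otx2-null aggregates grown without cytokines. Per the labels, EpiLC were harvested after 2 days in medium with 1% serum replacement, and aggregates after 6 days in medium with 15% serum replacement, when SSEA1 and CD61 positive cells were sorted. Per the labels, 100 ng of total RNA was primed with oligo-dT and made into biotin-labelled cRNA. The labels number the replicates but do not say how the cultures were made, and they name no slide for any array.

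The deposited intensity table is called non-normalized, but the authors had subtracted background and equalized the arrays before deposit. Its lowest value is -19.6 on 17 arrays and -18.7 on 4, its highest is 30894.6 on every array, and all columns hold nearly the same set of values. The deposited detection p-value of each probe and array, per the file headers, gives the chance of such a signal without the transcript. The authors' normalized table holds log2 values that rise with the deposited intensities along 1 curve, with about 110 units taken from bright probes, so dim signals lie near its floor. The series matrix holds the same log2 values as that table. Per the labels the authors used limma, without a version.

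In the intensity table the column of Otx2-null PGCLC replicate 2 stood in another probe order. Its rank correlation with the normalized column of that array was 0.00547, against 1 for the other arrays. The values were put back in order by the ranks of the normalized column, after which the correlation was 1 and 76 detection p-values differed between the tables. Detection p-values were therefore taken from the normalized table for every array.

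Background correction, an offset of 16, quantile normalization and log2 were applied to the intensities with neqc in limma 3.58.1 under R 4.3.3, which estimates the background from the detection p-values. Probes with detection p under 0.05 on at least 3 of the 21 arrays were kept, which left 21647 probes, 18156 of them with a gene name. Of all probes, 34885 name 1 gene, 18 several and 10378 none. Of several probes for a gene, the one with the highest mean over all arrays was used, giving 11649 genes. Tables were handled with the package data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

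The groups were fitted together in a limma model (lmFit and eBayes) with group as the only factor, so that 21 arrays shared the estimate of spread. From it came 12 comparisons of 2 groups and 2 contrasts of induction changes, Otx2-null against WT and Otx2/Blimp1-null against Otx2-null. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes in each comparison, with a threshold of 0.05. A gene not detected on any array of a group was given as a bound, with the lowest signal of a detected probe on each of its arrays (4.82 to 5.31 on the log2 scale) in place of its own value where that was lower. The overlap with WT induction counted genes called in the same direction in comparisons that share no array.

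Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. The 19 lists were written from general knowledge before the data were examined. They were early germ cell genes, late germ cell genes, naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesoderm, neural ectoderm, endoderm, trophoblast and amnion, and blood and endothelium. The others were DNA methylation and chromatin modifiers, the targets of BMP and SMAD, LIF and STAT3, FGF and ERK, and p53, mitotic cell cycle, hypoxia and glycolysis, dissociation stress, and cholesterol synthesis. Of their 332 genes, 310 had a named probe, and genes shared between lists count in each. Neural ectoderm kept 7 of 22 genes, the smallest share.

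Genes are named by a rule also fixed before the data were examined. It covers Otx2 and Prdm1, a panel of 22 germ cell, pluripotency and epiblast genes, and per comparison the 10 largest rises and 10 largest falls among called genes whose replicates do not overlap between groups, which chance gives for 10% of genes. It also covers up to 4 members of a described list with the smallest p and members that go against the median of their list. Where space was short, the values shown are a part of those the rule allows. The panel gene Hoxb1 and the Blimp1 gene Prdm1 had no kept probe, T was not analysed here, and Itgb3 and Fut4 lay near the floor. Another gene of the panel is not reported here.

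For arrays, depth was read as signal over background, and between 31.1% and 43.2% of probes were detected per array. Mean correlations within groups ran from 0.983 to 0.992. On simulated data with 3 arrays per group, changes of 0.5, 1 and 2 on the log2 scale were recovered for 19.4%, 92.5% and 100% of genes, with 8 false calls. For contrasts of changes they were 2.99%, 46.3% and 98.5%, with 4 false calls. With 1 list raised, it and 2 sharing its genes were called, but wrong splits of real arrays gave up to 47 of 228.

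Whether equal replicate numbers pair samples was checked by correlating the deviations of arrays from their group means. Only for WT EpiLC and Otx2-null EpiLC did every pair with the same number exceed 0.1 (0.135 to 0.289). No pairing was used in the model, and the replicate number was tried as a block.

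Each result was recomputed with 1 choice changed at a time. These were log2 of the signal plus a constant of 20.643 without background correction, the authors' normalized table, an offset of 50, no detection filter, a detection p under 0.01, the mean of the probes of a gene, each probe alone, array weights, a replicate block, only the groups compared, a change of at least 2-fold, and each array left out. Lists were also tested with fry and without shared genes. After seeing the data, 2 more were added, a correction for a trend with gene span (11640 genes) and a restriction to genes detected on all arrays compared. The series matrix was not run as it equals the normalized table, nor was a slide block, as no slide is named. Probes without a gene name were left out of the gene tests.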

Results

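RNA levels were measured on 21 one-colour bead arrays of mouse cells, in 7 groups of 3. Epiblast-like cells (EpiLC) were made from naive embryonic stem cells in 2 days with activin A and FGF2. They stand for the post-implantation epiblast from which germ cells arise. Primordial germ cell-like cells (PGCLC) were the SSEA1 and CD61 positive cells sorted from aggregates at day 6 of culture with BMP4, BMP8a, LIF, SCF and EGF. EpiLC and PGCLC came from the wild-type line E14Tg2a (WT), from a line without Otx2, a homeodomain transcription factor of the epiblast and anterior brain, and from a line without Otx2 and Blimp1. Blimp1 is encoded by Prdm1 and is a transcriptional repressor needed for germ cell specification. A further group held SSEA1 and CD61 positive cells from Otx2-null aggregates kept for 6 days in basal medium without cytokines. The series asks whether the sorted day-6 cells of the mutant lines resemble wild-type germ cell-like cells. Each genotype was a single line, so a difference between genotypes is also a difference between lines.

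Signals of 45281 probes were read on each array, and 11649 genes were tested. Detected probes numbered 14088 to 15861 on EpiLC arrays, 17527 to 19556 on WT and Otx2-null day-6 arrays and 15961 to 16507 on Otx2/Blimp1-null day-6 arrays. For arrays, their number, here 3 per group, limits the precision. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these samples. The median standard error of a log2 difference between groups was 0.18. Gene values without another unit are log2 differences, positive where the group named first was higher. Values after ± are standard errors for log2 differences and standard deviations for group means, with n = 3 arrays per group throughout.

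The arrays separated by stage along principal component 1, which held 63.8% of the variance. EpiLC arrays of all 3 lines lay between -74.0 and -44.7 on it, and WT and Otx2-null day-6 arrays lay between 55.5 and 65.8. The Otx2/Blimp1-null PGCLC arrays lay between these, from -2.68 to 3.68, and stood apart on component 2.

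**Figure D1:**
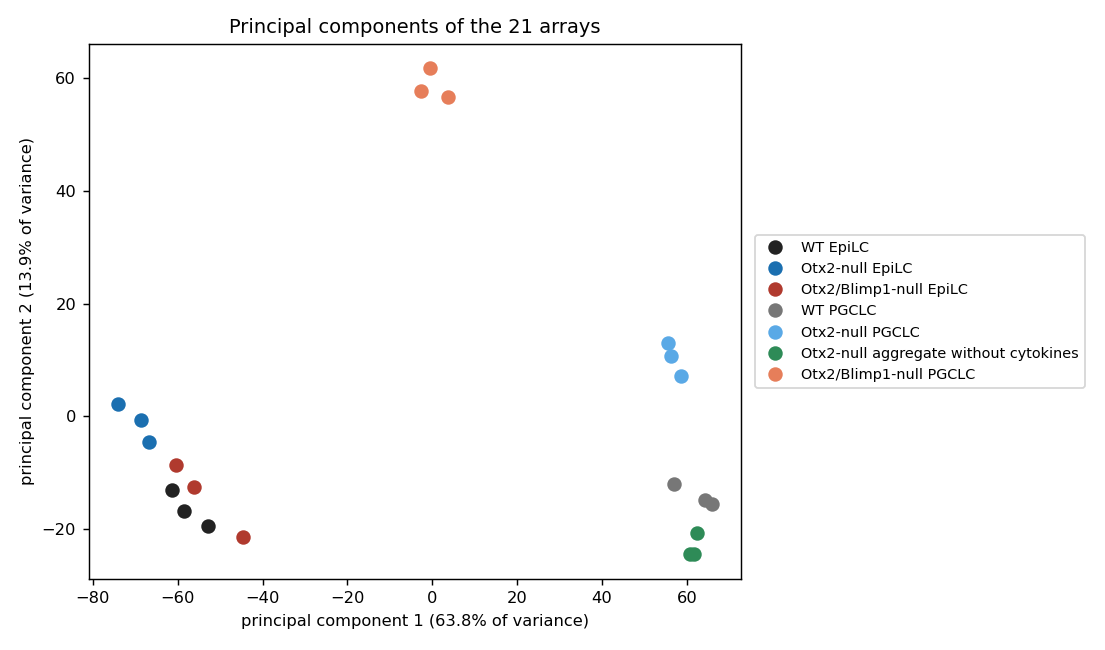
Each point is 1 array placed by its first and second principal components of the log2 signals, coloured by group. The 3 Otx2/Blimp1-null PGCLC arrays lie near 0 on component 1, between the EpiLC arrays and the other day-6 arrays.

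The probe for Otx2 was detected on every array and its signal was not lower in the lines described as lacking the gene. In EpiLC the log2 signal was 10.98 ± 0.24 in WT, 11.36 ± 0.10 in Otx2-null and 11.49 ± 0.09 in Otx2/Blimp1-null cells. At day 6 it was 7.63 ± 0.07 in WT PGCLC, 9.62 ± 0.22 in Otx2-null PGCLC, 9.34 ± 0.22 without cytokines and 10.39 ± 0.15 in Otx2/Blimp1-null PGCLC. The position of this probe relative to the deleted part is not known, so the signal does not test the genotype. Neither of the 2 Prdm1 probes was kept for testing. The brighter had a log2 signal of 4.64 ± 0.12 in WT PGCLC and 4.51 ± 0.13 in Otx2/Blimp1-null PGCLC, and was detected only on 2 arrays of the group without cytokines. Blimp1 loss was therefore not measurable here. Hoxb1 also had no probe kept for testing, and T was not analysed here.

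The step from WT EpiLC to WT PGCLC describes germ cell-like induction in unmodified cells. Most naive pluripotency genes and many germ cell genes rose, and many epiblast genes fell. Of these lists, only the naive one passed with an estimated correlation, and not the early germ cell (adjusted p = 0.0541) or epiblast list (adjusted p = 0.268). Tfap2c, a transcription factor of early germ cells, rose by a log2 fold change of 7.93 ± 0.16 (adjusted p = 9.56e-21). Kit, the receptor of stem cell factor, rose by 6.06 ± 0.18 (adjusted p = 3.06e-17), and Dppa3, a maternal and germ cell chromatin factor, rose by 4.79 ± 0.25 (adjusted p = 1.66e-13). Nanos3, an RNA-binding protein of germ cells, was not detected in WT EpiLC and was at least 8.03-fold higher, and Prdm14, a germ cell and naive pluripotency regulator, was at least 5.30-fold higher. Fgf5 and Pou3f1, which mark the post-implantation epiblast, changed by -4.23 ± 0.18 and -4.29 ± 0.24.

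Among the panel genes, Nanog rose by 2.98 ± 0.20, Dnd1, an RNA-binding protein of germ cells, by 1.94 ± 0.17, Sox2 by 2.19 ± 0.21 and Dazl, a later germ cell RNA-binding protein, by 1.51 ± 0.20. Id1, a target of BMP signals, rose by 3.97 ± 0.24. Dnmt3b, a de novo DNA methyltransferase, changed by -1.40 ± 0.17, and Otx2 by -3.35 ± 0.15. Ddx4, a late germ cell helicase, lay near background and was at least 1.59-fold lower in PGCLC. Pou5f1, the pluripotency factor Oct4, was at 0.07 ± 0.14 (adjusted p = 0.698). The largest rises also held Klf2, at least 173-fold higher, Igf2, an imprinted growth factor, at 7.76 ± 0.34, and Porcn, needed for Wnt secretion, at 5.60 ± 0.28. The largest falls were those of Cbr3, a carbonyl reductase, at -5.97 ± 0.21, Car4, a carbonic anhydrase, at -5.42 ± 0.20, Hopx at -5.15 ± 0.15 and Plac8 at -4.84 ± 0.26.

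Each of the 19 fixed gene lists is given with its members that passed the test, its median log2 fold change and the adjusted p of the list, and where bounded genes change the median it is also given at the bounds. Of these lists, naive pluripotency moved furthest in WT, with 17 of 18 higher, 0 lower and 1 not past the test (median 3.83, or 3.54 at the bounds, adjusted p = 2.87e-11). A list that passed is given a second p where it did not pass with an estimated correlation between genes. Examples of naive genes are Esrrb at 7.30 ± 0.15, Tfcp2l1 at 6.85 ± 0.15 and Nr5a2, at least 30.1-fold higher, all transcription factors of naive stem cells. The early germ cell list had 12 of 18 higher, 2 lower and 4 not past the test (median 2.07, adjusted p = 0.000326, adjusted p = 0.0541 with an estimated correlation). It included Tcl1 at 5.32 ± 0.21, while the Tudor proteins Tdrd12 and Tdrd5 went the other way at -3.09 ± 0.22 and -0.76 ± 0.20. Formative and primed epiblast genes had 5 of 20 higher, 11 lower and 4 not past the test (median -0.63, adjusted p = 0.021, adjusted p = 0.268 with an estimated correlation). Dnmt3l, a cofactor of DNA methylation, rose against that list by 2.14 ± 0.20, and Etv5 by 2.00 ± 0.22. A second kept probe gave 0.086 for Esrrb, and the authors' normalized table gave -0.28 for Tdrd5, neither past the test.

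Most targets of BMP and of LIF signals rose in WT PGCLC. BMP and SMAD targets had 9 of 9 higher and 0 lower (median 1.76, adjusted p = 0.000354), with Gata2 at least 10.9-fold higher and Bmp4 itself at 2.89 ± 0.21. LIF and STAT3 targets had 10 of 12 higher, 0 lower and 2 not past the test (median 1.98, adjusted p = 0.000326), with Klf5 at 4.21 ± 0.18, Klf4 at 3.65 ± 0.19 and Socs3, a feedback inhibitor of that pathway, at 3.30 ± 0.19. Most cholesterol synthesis genes fell, with 1 of 14 higher and 13 lower (median -1.69, adjusted p = 2.35e-05). These included Msmo1 at -2.83 ± 0.17, Idi1 at -2.43 ± 0.16 and Lss at -2.03 ± 0.15, all enzymes of the pathway, whereas the sterol isomerase Ebp rose by 1.30 ± 0.14. Dissociation stress genes had 9 of 12 higher, 1 lower and 2 not past the test (median 1.61, or 1.45 at the bounds, adjusted p = 0.0183, adjusted p = 0.2 with an estimated correlation), with the heat-shock protein Hspb1 at 3.49 ± 0.23 and Zfp36 at 1.81 ± 0.16, against Atf3 at -1.12 ± 0.16.

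Many markers of somatic lineages were also higher in the sorted WT cells, with only the mesoderm list past the test with an estimated correlation. The primitive streak and mesoderm list had 12 of 17 higher, 1 lower and 4 not past the test (median 0.93, or 0.66 at the bounds, adjusted p = 0.00217). Cdx2, a posterior homeobox gene, was at least 7.13-fold higher, Wnt5a at least 3.13-fold and Gata6 at least 4.10-fold higher, and Fgf8 was at least 1.79-fold lower. Trophoblast and amnion genes had 8 of 10 higher, 0 lower and 2 not past the test (median 1.80, or 1.19 at the bounds, adjusted p = 0.00462, adjusted p = 0.2 with an estimated correlation), with Tead4 at least 4.11-fold and Gata3 at least 2.17-fold higher. Endoderm genes had 11 of 15 higher, 2 lower and 2 not past the test (median 1.02, or 0.92 at the bounds, adjusted p = 0.0183, adjusted p = 0.0777 with an estimated correlation), with the basement membrane genes Lama1, at least 6.86-fold higher, and Col4a1 at 3.02 ± 0.22, and with Gata4 at least 1.43-fold and Apoa1 at least 1.22-fold lower. In the authors' normalized table Fgf8 gave -0.03 and Apoa1 -0.012, neither past the test, nor did Apoa1 pass after the correction for gene span (-0.24).

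The other lists did not shift past the threshold in WT. Late germ cell genes had 2 of 14 higher, 5 lower and 7 not past the test (median -0.12, adjusted p = 0.286), general pluripotency 6 of 13 higher, 2 lower and 5 not past the test (median 0.07, adjusted p = 0.567) and neural ectoderm 4 of 7 higher and 3 lower (median 0.74, adjusted p = 0.473). Blood and endothelium had 5 of 10 higher, 2 lower and 3 not past the test (median 0.52, or 0.22 at the bounds, adjusted p = 0.272), among which the embryonic globin gene Hbb-y was at least 7.01-fold higher. DNA methylation and chromatin modifiers had 7 of 15 higher, 4 lower and 4 not past the test (median 0.31, adjusted p = 0.272), FGF and ERK targets 6 of 12 higher, 2 lower and 4 not past the test (median 0.73, or 0.60 at the bounds, adjusted p = 0.292) and p53 targets 5 of 12 higher, 5 lower and 2 not past the test (median -0.17, adjusted p = 0.386). Mitotic cell cycle genes had 5 of 15 higher, 4 lower and 6 not past the test (median 0.13, adjusted p = 0.658) and hypoxia and glycolysis genes 4 of 16 higher, 8 lower and 4 not past the test (median -0.51, adjusted p = 0.164). For every list in this comparison, the counts adjusted over the list alone equalled those adjusted over all genes. In the limma test of all genes, 7320 changed, 4130 up and 3190 down, and 4022 of them by at least 2-fold.

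**Figure D2:**
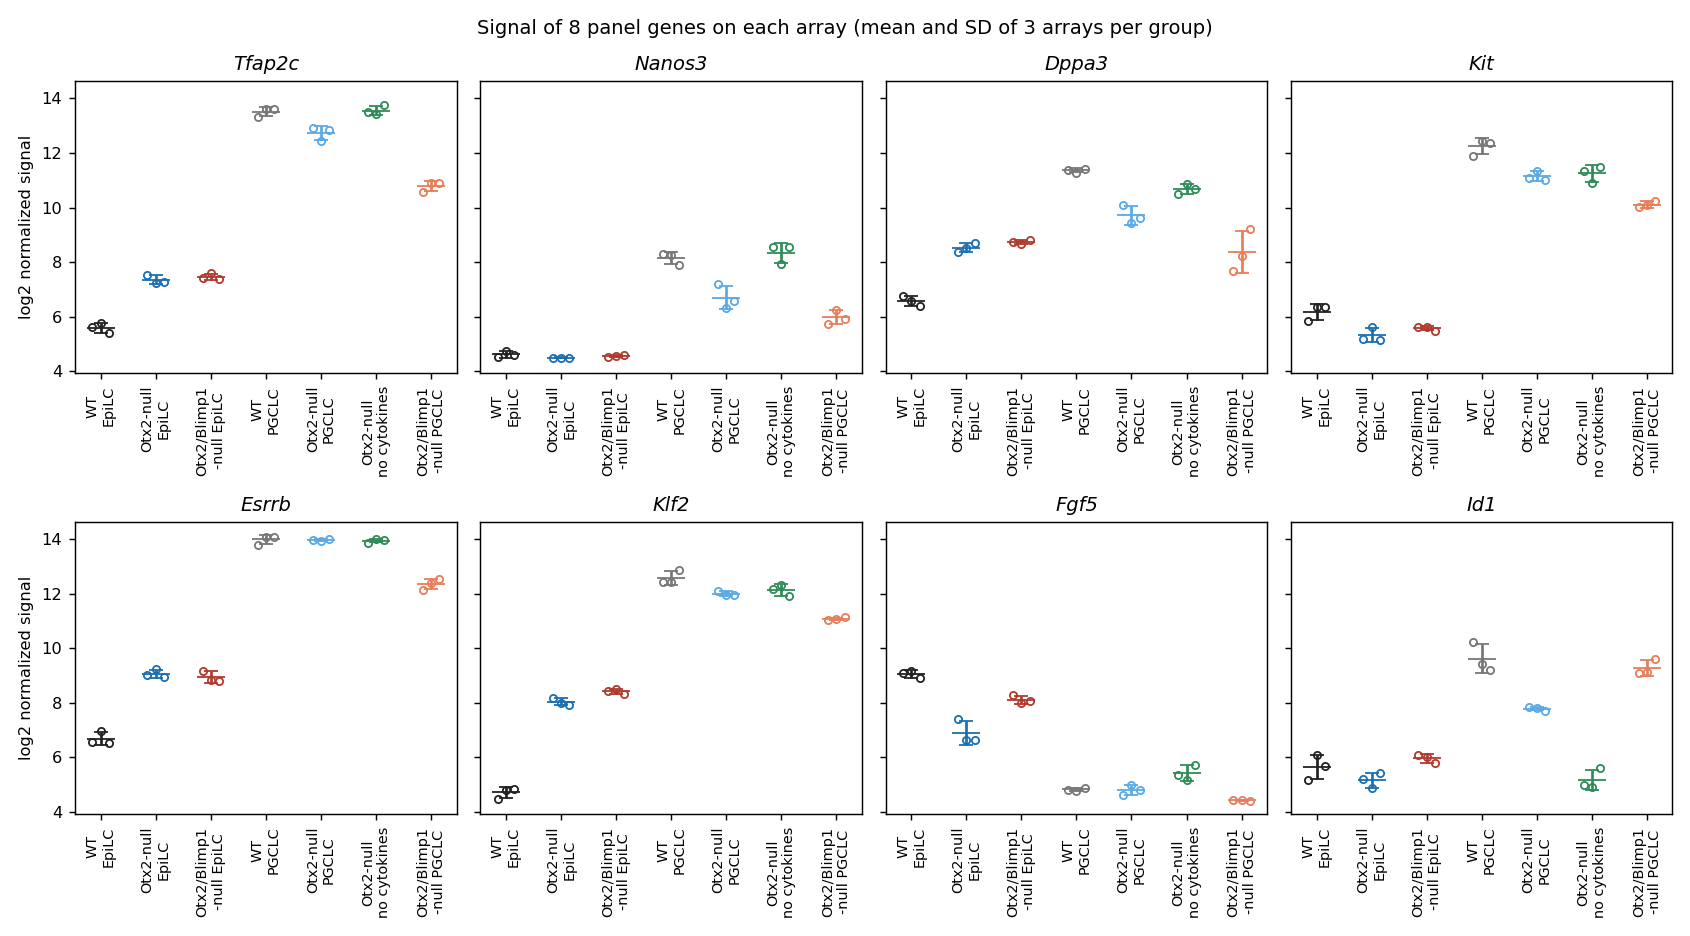
Log2 normalized signal of 8 panel genes on each array, as points, with the mean and SD of the 3 arrays in each group. Tfap2c lay at 13.5 in WT PGCLC, 12.7 in Otx2-null PGCLC, 13.6 without cytokines and 10.8 in Otx2/Blimp1-null PGCLC.

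Otx2-null cells taken through the same cytokine culture were compared with their own EpiLC. Several germ cell and naive genes named for WT also rose. Tfap2c rose by 5.39 ± 0.16 (adjusted p = 2.5e-17), Kit by 5.83 ± 0.18, Esrrb by 4.91 ± 0.15 and Klf2 by 3.97 ± 0.15. Prdm14 was at least 4.87-fold and Nanos3 at least 2.66-fold higher, and Dppa3 rose by 1.20 ± 0.25 (adjusted p = 0.000172). Pou3f1 changed by -3.68 ± 0.24, Dnmt3b by -2.14 ± 0.17 and Fgf5 by -2.09 ± 0.18. The second Esrrb probe gave 0.22, and in the authors' normalized table Nanos3 was at 0.45 and Fgf5 at -0.69, none past the test.

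Among the largest rises were Tfcp2l1, at least 181-fold higher, Tbx3, at least 29.3-fold higher, and Tcl1 at 5.38 ± 0.21. The largest falls included Cthrc1, a secreted protein with collagen-like repeats, at -5.06 ± 0.19, Tmem54, at least 29.5-fold lower, the growth factor Ptn, at least 17.1-fold lower, and the chemokine Cxcl12 at -4.31 ± 0.15. Naive pluripotency had 17 of 18 higher, 0 lower and 1 not past the test (median 3.17, or 2.77 at the bounds, adjusted p = 5.15e-10) and LIF and STAT3 targets 9 of 12 higher, 0 lower and 3 not past the test (median 2.05, or 1.84 at the bounds, adjusted p = 0.000322), with Klf5 at 5.44 ± 0.18 and Socs3 at 4.02 ± 0.19. Early germ cell genes had 11 of 18 higher, 3 lower and 4 not past the test (median 1.70, or 1.30 at the bounds, adjusted p = 0.00533, adjusted p = 0.209 with an estimated correlation), with Tdrd12 against the rest at -3.05 ± 0.22. Cholesterol synthesis had 1 of 14 higher, 12 lower and 1 not past the test (median -1.58, adjusted p = 1.98e-05), or 1 higher and 13 lower adjusted over the list alone, with Idi1 at -2.97 ± 0.16 and Lss at -2.23 ± 0.15.

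Somatic lists gave no shift past the threshold in Otx2-null PGCLC. Primitive streak and mesoderm genes had 2 of 17 higher, 2 lower and 13 not past the test (median -0.06, adjusted p = 0.76). Trophoblast and amnion genes had 2 of 10 higher, 4 lower and 4 not past the test (median -0.14, or -0.04 at the bounds, adjusted p = 0.76) and BMP and SMAD targets 6 of 9 higher, 1 lower and 2 not past the test (median 0.81, or 0.12 at the bounds, adjusted p = 0.11). Fgf8 changed by -2.89 ± 0.22, and the keratin gene Krt18 was at least 6.61-fold lower. In all, 7628 genes changed, 4179 up and 3449 down.

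Without cytokines, the sorted cells of Otx2-null aggregates were likewise set against Otx2-null EpiLC. Tfap2c rose by 6.21 ± 0.16 (adjusted p = 2.21e-18), Kit by 5.93 ± 0.18 and Dppa3 by 2.16 ± 0.25 (adjusted p = 5.14e-08). Nanos3 was at least 8.33-fold and Prdm14 at least 5.21-fold higher, and Dnd1 rose by 1.06 ± 0.17. Id1, which rose by 2.62 ± 0.24 with cytokines, was at 0.01 ± 0.24 (adjusted p = 0.988), and Dazl was at 0.34 ± 0.20 (adjusted p = 0.146). Pou3f1 changed by -3.83 ± 0.24 and Fgf5 by -1.47 ± 0.18. In the authors' normalized table the fall of Fgf5 did not pass (-0.67).

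Large rises in this group included the X-linked homeobox genes Rhox9 at 6.50 ± 0.28 and Rhox6 at 5.44 ± 0.28, Wnt7b, at least 46.5-fold higher, and Tfcp2l1, at least 142-fold higher. Large falls included Cthrc1, at least 32.1-fold lower, Cbr3 at -4.85 ± 0.21 and Ldha, a lactate dehydrogenase subunit, at -4.42 ± 0.22. Early germ cell genes had 12 of 18 higher, 3 lower and 3 not past the test (median 2.33, or 2.27 at the bounds, adjusted p = 0.00105, adjusted p = 0.108 with an estimated correlation) and naive pluripotency genes 16 of 18 higher, 0 lower and 2 not past the test (median 2.54, or 2.29 at the bounds, adjusted p = 1.27e-07). Late germ cell genes had 1 of 14 higher, 7 lower and 6 not past the test (median -0.68, or -0.66 at the bounds, adjusted p = 0.0338, adjusted p = 0.258 with an estimated correlation), with Taf7l at -1.96 ± 0.17 and Rnf17 at -2.05 ± 0.19. Taf7l did not pass in the authors' normalized table (-0.47), nor Rnf17 on a second probe (-0.20). Formative and primed epiblast had 5 of 20 higher, 11 lower and 4 not past the test (median -0.62, adjusted p = 0.0338, adjusted p = 0.379 with an estimated correlation), against which Lefty2, a Nodal antagonist, rose by 1.80 ± 0.17.

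LIF and STAT3 targets had 8 of 12 higher, 0 lower and 4 not past the test without cytokines (median 1.08, or 0.98 at the bounds, adjusted p = 0.0338, adjusted p = 0.0892 with an estimated correlation). Dissociation stress had 8 of 12 higher, 0 lower and 4 not past the test (median 0.80, adjusted p = 0.0432, adjusted p = 0.379 with an estimated correlation). Cholesterol synthesis had 1 of 14 higher, 12 lower and 1 not past the test (median -1.53, adjusted p = 8.13e-05, adjusted p = 0.0892 with an estimated correlation). Mesoderm genes had 3 of 17 higher, 3 lower and 11 not past the test (median -0.12, adjusted p = 0.825), or 3 higher and 2 lower adjusted over the list alone. Trophoblast and amnion genes had 3 of 10 higher, 4 lower and 3 not past the test (median -0.11, or -0.02 at the bounds, adjusted p = 0.963), where the mean, 0.21, lay on the other side of 0. In all, 7687 genes changed, 4174 up and 3513 down.

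Cells without Otx2 and Blimp1 were compared with their own EpiLC after the cytokine culture. Most naive genes rose and most epiblast genes fell. Tfap2c rose by 3.33 ± 0.16 (adjusted p = 8.88e-14), Kit by 4.53 ± 0.18 and Dazl by 3.83 ± 0.20 (adjusted p = 5.01e-13), and Prdm14 was at least 3.52-fold and Nanos3 at least 1.73-fold higher. Dnd1 changed by -1.02 ± 0.17 (adjusted p = 3.47e-05), and Dppa3 was at -0.38 ± 0.25 (adjusted p = 0.233). Pou3f1 changed by -5.24 ± 0.24 and Dnmt3b by -4.07 ± 0.17, and Fgf5 was at least 8.41-fold lower. In the authors' normalized table Nanos3 gave 0.05 and Prdm14 0.61, neither past the test, and without Otx2/Blimp1-null PGCLC replicate 3 the fall of Dppa3 passed at -0.79.

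Large rises included Tfcp2l1 at 5.97 ± 0.15, Tbx3 at 4.93 ± 0.20 and Aurkc, a meiotic kinase, at 4.92 ± 0.17, and large falls were Cxcl12, at least 30.4-fold lower, and Cdkn1c, a cell cycle inhibitor, at -4.50 ± 0.24. Naive pluripotency had 15 of 18 higher, 0 lower and 3 not past the test (median 2.95, adjusted p = 1e-15) and LIF and STAT3 targets 9 of 12 higher, 1 lower and 2 not past the test (median 1.07, adjusted p = 6.66e-06). Formative and primed epiblast had 1 of 20 higher, 14 lower and 5 not past the test (median -1.32, adjusted p = 3.15e-07), and early germ cell genes 11 of 18 higher, 3 lower and 4 not past the test (median 1.38, or 1.02 at the bounds, adjusted p = 0.00301, adjusted p = 0.123 with an estimated correlation). Endoderm had 9 of 15 higher, 0 lower and 6 not past the test (median 0.89, or 0.39 at the bounds, adjusted p = 0.0041), or 9 higher and 1 lower adjusted over the list alone, with Gsc at least 3.24-fold higher.

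Cholesterol synthesis had 1 of 14 higher, 11 lower and 2 not past the test in these cells (median -1.51, adjusted p = 6.51e-06), or 2 higher and 11 lower adjusted over the list alone. Hypoxia and glycolysis had 3 of 16 higher, 11 lower and 2 not past the test (median -0.79, adjusted p = 0.018, adjusted p = 0.359 with an estimated correlation), with Egln3, an oxygen sensor, at -2.82 ± 0.16 and against it the glucose transporter Slc2a3 at 2.15 ± 0.17. p53 targets had 1 of 12 higher, 7 lower and 4 not past the test (median -0.64, adjusted p = 0.0472, adjusted p = 0.461 with an estimated correlation), with Bbc3, which encodes the cell death protein Puma, at -1.48 ± 0.16, or -0.41 and -0.21 and not past the test on its other probes, and against it Ei24 at 0.70 ± 0.16. In all, 5038 genes changed, 2384 up and 2654 down.

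How much of the WT induction each other population showed was asked with no array shared between the contrasts. Of the 7320 WT genes, 5902 (80.6%) changed the same way in Otx2-null PGCLC, 5853 (80.0%) without cytokines and 2965 (40.5%) in Otx2/Blimp1-null PGCLC. Genes called in opposite directions numbered 129, 145 and 762. Independent lists of these sizes would share 2426, 2442 and 1572 genes in the same direction. Across genes, which are not independent, the log2 fold changes correlated with those of WT at r = 0.865, 0.851 and 0.514.

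**Figure D3:**
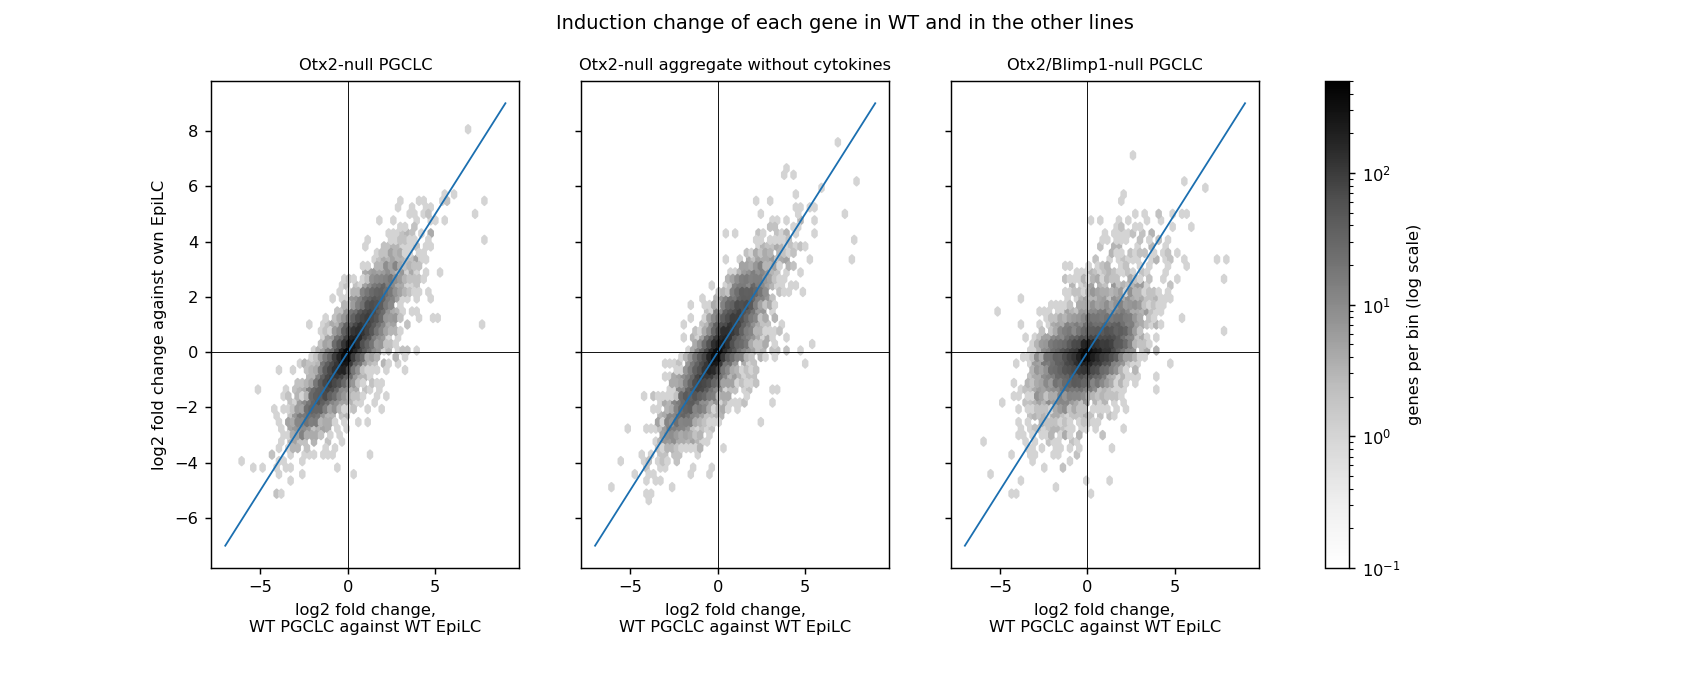
Each panel bins the 11649 genes by their log2 fold change from EpiLC to day 6 in WT, on the horizontal axis, and in 1 other population, on the vertical axis, with the line of equal change in blue. The cloud is flattest for Otx2/Blimp1-null PGCLC, where r across genes is 0.514.

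The size of the induction change itself differed from WT in Otx2-null cells for 1916 genes, 930 upward and 986 downward. The difference was -3.59 ± 0.35 for Dppa3 and -2.54 ± 0.23 for Tfap2c (-0.52 and not past the test on its second probe), genes whose level was already higher in Otx2-null EpiLC. Primitive streak and mesoderm genes differed downward as a list, with 0 of 17 higher, 10 lower and 7 not past the test (median -1.15, adjusted p = 7.57e-09), and so did trophoblast and amnion genes, with 0 of 10 higher, 8 lower and 2 not past the test (median -1.56, adjusted p = 7.32e-08). Between Otx2/Blimp1-null and Otx2-null cells the change differed for 5686 genes, 2340 upward and 3346 downward, among them Tfap2c by -2.06 ± 0.23 and Dnmt3b by -1.93 ± 0.24.

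At day 6, Otx2-null PGCLC were compared directly with WT PGCLC. Many mesoderm and trophoblast genes and BMP targets were lower than in WT, and so were several germ cell genes. Prdm14 was at 0.02 ± 0.17 (adjusted p = 0.961) and Esrrb at -0.01 ± 0.15 (adjusted p = 0.973). Nanos3 was lower at -1.45 ± 0.20 (adjusted p = 9.76e-06), Dppa3 at -1.64 ± 0.25 (adjusted p = 3.11e-05), Kit at -1.09 ± 0.18 (adjusted p = 0.000151) and Tfap2c at -0.78 ± 0.16 (adjusted p = 0.00102). Dazl was higher by 0.73 ± 0.20 (adjusted p = 0.0121) and Sox2 by 1.45 ± 0.21 (adjusted p = 2.3e-05), and Nanog was at -0.44 ± 0.20 (adjusted p = 0.119). Other kept probes gave 0.42 for Kit and -0.14 for Sox2, neither past the test, and 1.51 for Nanog, past it, and the mean of its probes gave -0.33 for Kit, not past it. Dazl did not pass without WT PGCLC replicate 1 (0.52), Otx2-null PGCLC replicate 2 (0.67) or replicate 3 (0.61), while Nanog passed without that last array (-0.62) and with array weights (-0.43).

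The largest differences of named genes were losses. Acta2, smooth muscle actin, was lower at -6.41 ± 0.24 (adjusted p = 1.01e-14), Igf2 at -6.13 ± 0.34 (adjusted p = 8.98e-12), Dlk1, another imprinted growth regulator, at -4.98 ± 0.27 and the keratin gene Krt8 at -4.79 ± 0.31. Igfbp5, an IGF binding protein, was lower at -4.30 ± 0.27, and the myelin gene Pmp22 was at least 12.9-fold lower. The largest gains were Zscan4c, a gene of the 2-cell embryo, at 2.73 ± 0.47 (adjusted p = 0.000186), Sall3 at 2.67 ± 0.22, Krt42 at 2.62 ± 0.20 and Vwf, von Willebrand factor, at 2.36 ± 0.21.

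Primitive streak and mesoderm had 1 of 17 higher, 10 lower and 6 not past the test in this comparison (median -0.76, adjusted p = 1.58e-07), or 1 higher and 11 lower adjusted over the list alone. Cdx2 was at least 8.34-fold, Wnt5a at least 3.65-fold and Msx1 at least 4.44-fold lower, and Wnt3a went the other way at 0.49 ± 0.14, and its call was lost in the authors' normalized table (0.016), without background correction (adjusted p = 0.259) and without Otx2-null PGCLC replicate 3 (0.40). Trophoblast and amnion had 1 of 10 higher, 8 lower and 1 not past the test (median -1.41, or -1.26 at the bounds, adjusted p = 4.89e-08), with Krt18 at least 9.35-fold lower and Tead4 higher at 0.47 ± 0.14. Tead4 did not pass on its second probe (0.078), in the mean of its probes (0.27), without background correction (0.45), without WT PGCLC replicate 3 (0.41) or Otx2-null PGCLC replicate 1 (0.43) or 2 (0.40). BMP and SMAD targets had 0 of 9 higher, 7 lower and 2 not past the test (median -1.12, adjusted p = 1.73e-06), with Id1 at -1.83 ± 0.24 and Id3 at -1.82 ± 0.26.

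Further lists passed here only with the preset correlation. Endoderm had 3 of 15 higher, 6 lower and 6 not past the test (median -0.21, adjusted p = 0.0277, adjusted p = 0.122 with an estimated correlation), or 3 higher and 7 lower adjusted over the list alone, with Amn at -2.51 ± 0.23. Neural ectoderm had 1 of 7 higher, 4 lower and 2 not past the test (median -1.10, adjusted p = 0.0197, adjusted p = 0.122 with an estimated correlation). Blood and endothelium had 1 of 10 higher, 3 lower and 6 not past the test (median -0.31, adjusted p = 0.0159, adjusted p = 0.0933 with an estimated correlation), with Hbb-y at least 8.19-fold lower. General pluripotency had 4 of 13 higher, 0 lower and 9 not past the test (median 0.06, adjusted p = 0.039, adjusted p = 0.249 with an estimated correlation). For p53 targets the numbers were 4 of 12 higher, 0 lower and 8 not past the test (median 0.30, adjusted p = 0.00324, adjusted p = 0.171 with an estimated correlation). Among these p53 targets was Ccng1, higher at 1.86 ± 0.23. Dissociation stress had 0 of 12 higher, 7 lower and 5 not past the test (median -0.47, or -0.20 at the bounds, adjusted p = 0.011, adjusted p = 0.146 with an estimated correlation), with Jun at -1.31 ± 0.15. Early germ cell genes had 1 of 18 higher, 6 lower and 11 not past the test (median -0.12, adjusted p = 0.181) and naive pluripotency 7 of 18 higher, 3 lower and 8 not past the test (median 0.03, adjusted p = 0.25). In all, 2481 genes differed, 1040 higher and 1441 lower, and 642 of them by at least 2-fold.

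The cytokine-free Otx2-null cells were set against WT PGCLC. Several mesoderm, endoderm and blood genes and LIF targets were lower, while Tfap2c, Nanos3 and Prdm14 did not differ past the threshold. Tfap2c was at 0.04 ± 0.16 (adjusted p = 0.915), Nanos3 at 0.20 ± 0.20 (adjusted p = 0.552) and Prdm14 at 0.12 ± 0.17 (adjusted p = 0.697). Dppa3 was lower at -0.68 ± 0.25 (adjusted p = 0.0478), Kit at -0.99 ± 0.18 (adjusted p = 0.000327), Dazl at -1.33 ± 0.20 (adjusted p = 3.25e-05) and Nanog at -0.58 ± 0.20 (adjusted p = 0.0323). Id1 was lower at -4.45 ± 0.24 (adjusted p = 5.44e-12), Klf4 at -2.45 ± 0.19 and Socs3 at -2.60 ± 0.19. Dppa3 did not pass without any 1 of the 6 arrays (-0.77 to -0.58), nor Nanog without any 1 but WT PGCLC replicate 1 (-0.61 to -0.40). Both also lost the call in the authors' normalized table (adjusted p = 0.252 and 0.0663), without a detection filter (0.0975 and 0.0527) and after the correction for gene span (0.068 and 0.0524), and Dppa3 without background correction (0.0609). Other kept probes gave 0.57 for Kit, not past the test, and 1.13 for Nanog and 0.53 for Tfap2c, both past it, and the mean of probes -0.21 for Kit and 0.28 for Nanog, neither past it.

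Large losses were again Acta2, at least 75.1-fold lower, Dlk1 at -5.26 ± 0.27, Krt8 at -4.37 ± 0.31 and Igf2 at -3.77 ± 0.34, and also Cidea, a lipid droplet protein, at -4.71 ± 0.20. The largest gains included Igf1, a growth factor, at 3.06 ± 0.19 and Mocos at 2.84 ± 0.15, and Lefty1 was higher by 2.08 ± 0.22. Primitive streak and mesoderm had 2 of 17 higher, 11 lower and 4 not past the test (median -0.73, adjusted p = 1.37e-06), or 2 higher and 12 lower adjusted over the list alone. Endoderm had 1 of 15 higher, 8 lower and 6 not past the test (median -0.57, adjusted p = 0.000303). Blood and endothelium had 0 of 10 higher, 4 lower and 6 not past the test (median -0.37, adjusted p = 0.000693) and trophoblast and amnion 1 of 10 higher, 6 lower and 3 not past the test (median -1.32, or -1.26 at the bounds, adjusted p = 0.000114, adjusted p = 0.0675 with an estimated correlation).

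LIF and STAT3 targets had 0 of 12 higher, 6 lower and 6 not past the test against WT (median -0.34, or -0.21 at the bounds, adjusted p = 0.00141), with Stat3 itself at -1.73 ± 0.23. FGF and ERK targets had 1 of 12 higher, 7 lower and 4 not past the test (median -0.75, adjusted p = 0.000979), or 1 higher and 9 lower adjusted over the list alone, with Etv4 at -1.87 ± 0.15 and against it Dusp4 at 1.60 ± 0.18, or 0.20 and 0.38 and not past the test on its other probes. BMP and SMAD targets had 2 of 9 higher, 5 lower and 2 not past the test (median -1.03, adjusted p = 0.00489, adjusted p = 0.093 with an estimated correlation). General pluripotency had 4 of 13 higher, 0 lower and 9 not past the test (median 0.28, adjusted p = 0.0156, adjusted p = 0.203 with an estimated correlation). For p53 targets the numbers were 4 of 12 higher, 1 lower and 7 not past the test (median 0.37, adjusted p = 0.0371, adjusted p = 0.343 with an estimated correlation), and dissociation stress had 0 of 12 higher, 5 lower and 7 not past the test (median -0.52, or -0.31 at the bounds, adjusted p = 0.0245, adjusted p = 0.226 with an estimated correlation). The list of early germ cell genes had 5 of 18 higher, 3 lower and 10 not past the test (median 0.05, adjusted p = 0.183). In all, 2841 genes differed, 1181 higher and 1660 lower, and 764 by at least 2-fold.

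Sorted Otx2-null cells without and with cytokines were compared. Without cytokines, Nanos3 was higher by 1.65 ± 0.20 (adjusted p = 1.93e-06), Tfap2c by 0.81 ± 0.16 (adjusted p = 0.000807), Dppa3 by 0.97 ± 0.25 (adjusted p = 0.00805) and Dnd1 by 0.67 ± 0.17 (adjusted p = 0.00808). Dazl was lower at -2.06 ± 0.20 (adjusted p = 1.29e-07) and Id1 at -2.62 ± 0.24 (adjusted p = 5.22e-08). Zscan4c was lower at -5.59 ± 0.47 (adjusted p = 1.26e-08), and so were Tcstv1, also of the 2-cell embryo, at -3.48 ± 0.26 and Pramel20 at -4.07 ± 0.41. Igf1 was higher by 2.45 ± 0.19, Igf2 by 2.36 ± 0.34 and Car12 by 2.20 ± 0.19. Dnd1 did not pass without replicate 2 of the group without cytokines (0.56), nor Dppa3 without Otx2-null PGCLC replicate 2 (0.82) or in the authors' normalized table (1.07).

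LIF and STAT3 targets had 0 of 12 higher, 5 lower and 7 not past the test (median -0.27, adjusted p = 0.000117), with Socs3 at -2.79 ± 0.19, Klf4 at -2.27 ± 0.19 and Gbx2 at -2.40 ± 0.23. Early germ cell genes had 8 of 18 higher, 1 lower and 9 not past the test (median 0.19, adjusted p = 0.00214, adjusted p = 0.182 with an estimated correlation), with Rhox6 at 1.75 ± 0.28 and against it Dppa2 at -1.12 ± 0.25. Late germ cell genes had 0 of 14 higher, 4 lower and 10 not past the test (median -0.26, or -0.15 at the bounds, adjusted p = 0.00727, adjusted p = 0.182 with an estimated correlation). Naive pluripotency had 1 of 18 higher, 5 lower and 12 not past the test (median -0.18, adjusted p = 0.00727, adjusted p = 0.183 with an estimated correlation). Mitotic cell cycle genes had 0 of 15 higher, 1 lower and 14 not past the test (median -0.21, adjusted p = 0.0344, adjusted p = 0.304 with an estimated correlation), where Nusap1, at -0.61 ± 0.19, was the member that passed. Nusap1 did not pass on its other probes (-0.18 and -0.70), without Otx2-null PGCLC replicate 1 (-0.55) or 3 (-0.55) or without cytokine-free replicate 1 (-0.51) or 2 (-0.48), nor in the model of these 6 arrays alone (adjusted p = 0.0578). BMP and SMAD targets did not shift as a list, with 2 of 9 higher, 2 lower and 5 not past the test (median 0.08, adjusted p = 0.705). In all, 1820 genes differed, 850 higher and 970 lower, and 476 by at least 2-fold.

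At day 6, Otx2/Blimp1-null were set against Otx2-null PGCLC. Several germ cell genes and DNA methylation genes were lower, but neither list passed with an estimated correlation (adjusted p = 0.576 for each). Tfap2c was lower at -1.95 ± 0.16 (adjusted p = 4.61e-09), Dnd1 at -1.69 ± 0.17 (adjusted p = 5.08e-08), Dppa3 at -1.35 ± 0.25 (adjusted p = 8.23e-05), Nanos3 at -0.72 ± 0.20 (adjusted p = 0.00408) and Prdm14 at -0.57 ± 0.17 (adjusted p = 0.00738). Dazl was higher by 1.10 ± 0.20 (adjusted p = 1e-04), Id1 by 1.48 ± 0.24, and Nanog was at 0.28 ± 0.20 (adjusted p = 0.262). Esrrb was lower at -1.62 ± 0.15, Klf2 at -0.93 ± 0.15 and Sox2 at -1.33 ± 0.21, while second probes gave -0.068 for Esrrb and 0.15 for Sox2, neither past the test. Nanos3 did not pass in the authors' normalized table (-0.40) or without Otx2-null PGCLC replicate 1 (-0.48), nor Prdm14 without background correction (-0.55).

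The largest gains were the ribosomal protein paralogue genes Rpl39l at 3.28 ± 0.19 and Rpl22l1 at 3.00 ± 0.24, the protease inhibitor gene Spink1 at 3.27 ± 0.27 and Cox7b, of the respiratory chain, at 2.81 ± 0.29. The largest losses were Zc3h13, of the RNA methylation complex, at -3.40 ± 0.38, Wnt7b at -3.36 ± 0.23, the epithelial splicing factor Esrp1 at -3.16 ± 0.22 and Rhox9 at -2.90 ± 0.28. Early germ cell genes had 1 of 18 higher, 12 lower and 5 not past the test (median -0.91, adjusted p = 0.0109, adjusted p = 0.576 with an estimated correlation), or 2 higher and 13 lower adjusted over the list alone, with Ifitm3 at -0.93 ± 0.15 and against it Mns1 at 0.66 ± 0.16. DNA methylation and chromatin modifiers had 0 of 15 higher, 12 lower and 3 not past the test (median -1.24, adjusted p = 0.000987, adjusted p = 0.576 with an estimated correlation), with the maintenance methyltransferase Dnmt1 at -1.68 ± 0.19, Dnmt3b at -1.35 ± 0.17 and the Polycomb subunit Suz12 at -1.55 ± 0.15. Other probes gave -0.39 for Dnmt3b and -0.014 for Suz12, neither past the test. The other 17 lists did not pass, among them naive pluripotency with 1 of 18 higher, 10 lower and 7 not past the test (median -0.70, adjusted p = 0.136) and mesoderm with 1 of 17 higher, 1 lower and 15 not past the test (median -0.05, adjusted p = 0.992). In all, 5625 genes differed, 2332 higher and 3293 lower, and 2065 by at least 2-fold.

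Against WT PGCLC, the Otx2/Blimp1-null cells were lower in several germ cell genes and somatic markers, while Dazl, Stk31 and Dppa2 were higher. With an estimated correlation the early germ cell, mesoderm and trophoblast lists did not pass (adjusted p = 0.325, 0.051 and 0.234). Dppa3 was lower at -3.00 ± 0.25 (adjusted p = 9.51e-10), Tfap2c at -2.72 ± 0.16 (adjusted p = 5.78e-12), Dnd1 at -2.34 ± 0.17, Nanos3 at -2.17 ± 0.20 (adjusted p = 4.4e-09) and Kit at -2.13 ± 0.18. Dazl was higher by 1.83 ± 0.20 (adjusted p = 8.49e-08), and Nanog was at -0.16 ± 0.20 (adjusted p = 0.505). Second probes gave -0.29 for Kit, not past the test, and 1.73 for Nanog, past it, where the mean of probes gave 0.78, also past it. Acta2 was at least 68.4-fold lower, Igf2 changed by -6.07 ± 0.34 and Dlk1 by -5.50 ± 0.27, and Spink1 was among the largest gains at 5.16 ± 0.27.

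The early germ cell list had 3 of 18 higher, 13 lower and 2 not past the test against WT (median -0.78, adjusted p = 0.0112, adjusted p = 0.325 with an estimated correlation), with Stk31 and Dppa2 against the rest at 1.11 ± 0.25 and 0.92 ± 0.25. Primitive streak and mesoderm had 0 of 17 higher, 12 lower and 5 not past the test (median -0.87, or -0.61 at the bounds, adjusted p = 0.003, adjusted p = 0.051 with an estimated correlation), with Cdx2 at least 7.67-fold lower. Trophoblast and amnion genes had 0 of 10 higher, 9 lower and 1 not past the test (median -1.90, or -1.52 at the bounds, adjusted p = 0.000401, adjusted p = 0.234 with an estimated correlation), with Gata2 at -3.10 ± 0.17. DNA methylation and chromatin modifiers had 1 of 15 higher, 9 lower and 5 not past the test (median -0.81, adjusted p = 0.0165, adjusted p = 0.4 with an estimated correlation), or 1 higher and 10 lower adjusted over the list alone, with Dnmt3l at -2.74 ± 0.20. BMP and SMAD targets had 1 of 9 higher, 6 lower and 2 not past the test (median -0.68, adjusted p = 0.0327, adjusted p = 0.325 with an estimated correlation), with Hey1 at -3.25 ± 0.19, and dissociation stress 0 of 12 higher, 8 lower and 4 not past the test (median -0.73, adjusted p = 0.0389, adjusted p = 0.347 with an estimated correlation), or 9 lower adjusted over the list alone. In all, 6602 genes differed, 2618 higher and 3984 lower, and 3009 by at least 2-fold.

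The starting EpiLC of the Otx2-null line already differed from WT EpiLC. Several naive genes were higher and Fgf5 was lower. Klf2 was at least 7.39-fold higher, Esrrb was higher by 2.38 ± 0.15 (adjusted p = 1.63e-10), Dppa3 by 1.95 ± 0.25 (adjusted p = 4.17e-06), Tfap2c by 1.76 ± 0.16 (adjusted p = 3.56e-08), Sox2 by 1.27 ± 0.21 and Nanog by 0.85 ± 0.20 (adjusted p = 0.00328). Fgf5 was lower at -2.17 ± 0.18 (adjusted p = 9.82e-09) and Kit at -0.86 ± 0.18, and Pou3f1 was at -0.47 ± 0.24 (adjusted p = 0.181). Second probes gave 0.19 for Esrrb, -0.18 for Tfap2c and 0.085 for Kit, none past the test, nor did Kit pass in the authors' normalized table (-0.052) or in the mean of its probes (-0.39). Acta2 was lower at -4.94 ± 0.24 (adjusted p = 1.58e-12) and Hopx at -2.88 ± 0.15, and the tight junction gene Cldn5 was higher at 3.29 ± 0.26. Naive pluripotency was the list that shifted, with 8 of 18 higher, 2 lower and 8 not past the test (median 0.42, or 0.33 at the bounds, adjusted p = 3.07e-05, adjusted p = 0.0793 with an estimated correlation), and Tfcp2l1 and Klf5 went against it, Tfcp2l1 at least 1.12-fold lower and Klf5 at -0.52 ± 0.18. Klf5 did not pass without any 1 array but WT EpiLC replicate 2 (-0.56 to -0.42), with array weights (adjusted p = 0.0865), without background correction (0.0553), with an offset of 50 (0.0503), without a detection filter (0.0535) or after the correction for gene span (0.05), and in the authors' normalized table Tfcp2l1 and Rhox6 did not pass (-0.015 and -0.64). The early germ cell list had 5 of 18 higher, 4 lower and 9 not past the test (median 0.14, adjusted p = 0.45), with Rhox6 lower at -1.91 ± 0.28, and formative and primed epiblast 3 of 20 higher, 4 lower and 13 not past the test (median 0.19, adjusted p = 0.777). In all, 2183 genes differed, 958 higher and 1225 lower, 566 by at least 2-fold. Fitted on these 6 arrays alone, the count was 1049, and Klf5 and Tfcp2l1 did not pass (adjusted p = 0.0806 and 0.0758).

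EpiLC without Otx2 and Blimp1 differed by small amounts from EpiLC without Otx2. Thbs2, a matrix thrombospondin, was higher by 1.93 ± 0.18 (adjusted p = 1.25e-06), Fgf5 was higher by 1.22 ± 0.18 (adjusted p = 0.000363) and Pou3f1 by 0.89 ± 0.24 (adjusted p = 0.0145). Snhg16, a non-coding RNA, was lower at -1.88 ± 0.28 and Cep152, of the centrosome, at -1.70 ± 0.17, and Tfap2c was at 0.11 ± 0.16 (adjusted p = 0.703). Formative and primed epiblast had 4 of 20 higher, 0 lower and 16 not past the test (median 0.42, adjusted p = 0.0311, adjusted p = 0.434 with an estimated correlation), or 5 higher adjusted over the list alone, with Cldn6 at 0.94 ± 0.18. Late germ cell genes had 0 of 14 higher, 1 lower and 13 not past the test (median -0.28, adjusted p = 0.0311, adjusted p = 0.434 with an estimated correlation), with Asz1 at -0.82 ± 0.24. Asz1 did not pass in the authors' normalized table (-0.19) or without replicate 1 or 2 of either group (-0.80 to -0.55), nor Pou3f1 without Otx2/Blimp1-null EpiLC replicate 1 (0.74). In all, 1864 genes differed, 1141 higher and 723 lower, 134 by at least 2-fold. Fitted on these 6 arrays alone, 36 genes passed, and Fgf5, Pou3f1, Cldn6 and Asz1 did not (adjusted p = 0.0513, 0.054, 0.0581 and 0.131). The count was 1068 with array weights, 598 without Otx2/Blimp1-null EpiLC replicate 1 and 1167 without Otx2-null EpiLC replicate 3.

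Set against WT EpiLC, the EpiLC without Otx2 and Blimp1 were higher in several naive genes and lower in Fgf5. Klf2 was at least 9.67-fold higher, Esrrb was higher at 2.25 ± 0.15, Dppa3 at 2.17 ± 0.25 and Tfap2c at 1.87 ± 0.16, and Fgf5 was lower at -0.94 ± 0.18 (adjusted p = 0.000654). Second probes gave 0.071 for Esrrb and 0.01 for Tfap2c, neither past the test. Fgf8 was higher at 3.00 ± 0.22, Acta2 lower at -4.12 ± 0.24 and the stress response gene Ddit3 lower at -2.62 ± 0.16. Naive pluripotency had 9 of 18 higher, 0 lower and 9 not past the test (median 0.49, or 0.43 at the bounds, adjusted p = 5.05e-06). Formative and primed epiblast had 8 of 20 higher, 2 lower and 10 not past the test (median 0.31, adjusted p = 0.0307, adjusted p = 0.522 with an estimated correlation), or 9 higher adjusted over the list alone, with Dnmt3l at 1.51 ± 0.20 and against it Fgf5. p53 targets had 3 of 12 higher, 0 lower and 9 not past the test (median 0.40, adjusted p = 0.0307, adjusted p = 0.522 with an estimated correlation), or 6 higher adjusted over the list alone, with Cdkn1a, the inhibitor p21, at 0.69 ± 0.17. In all, 2112 genes differed, 1105 higher and 1007 lower, and 507 by at least 2-fold.

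**Figure D4:**
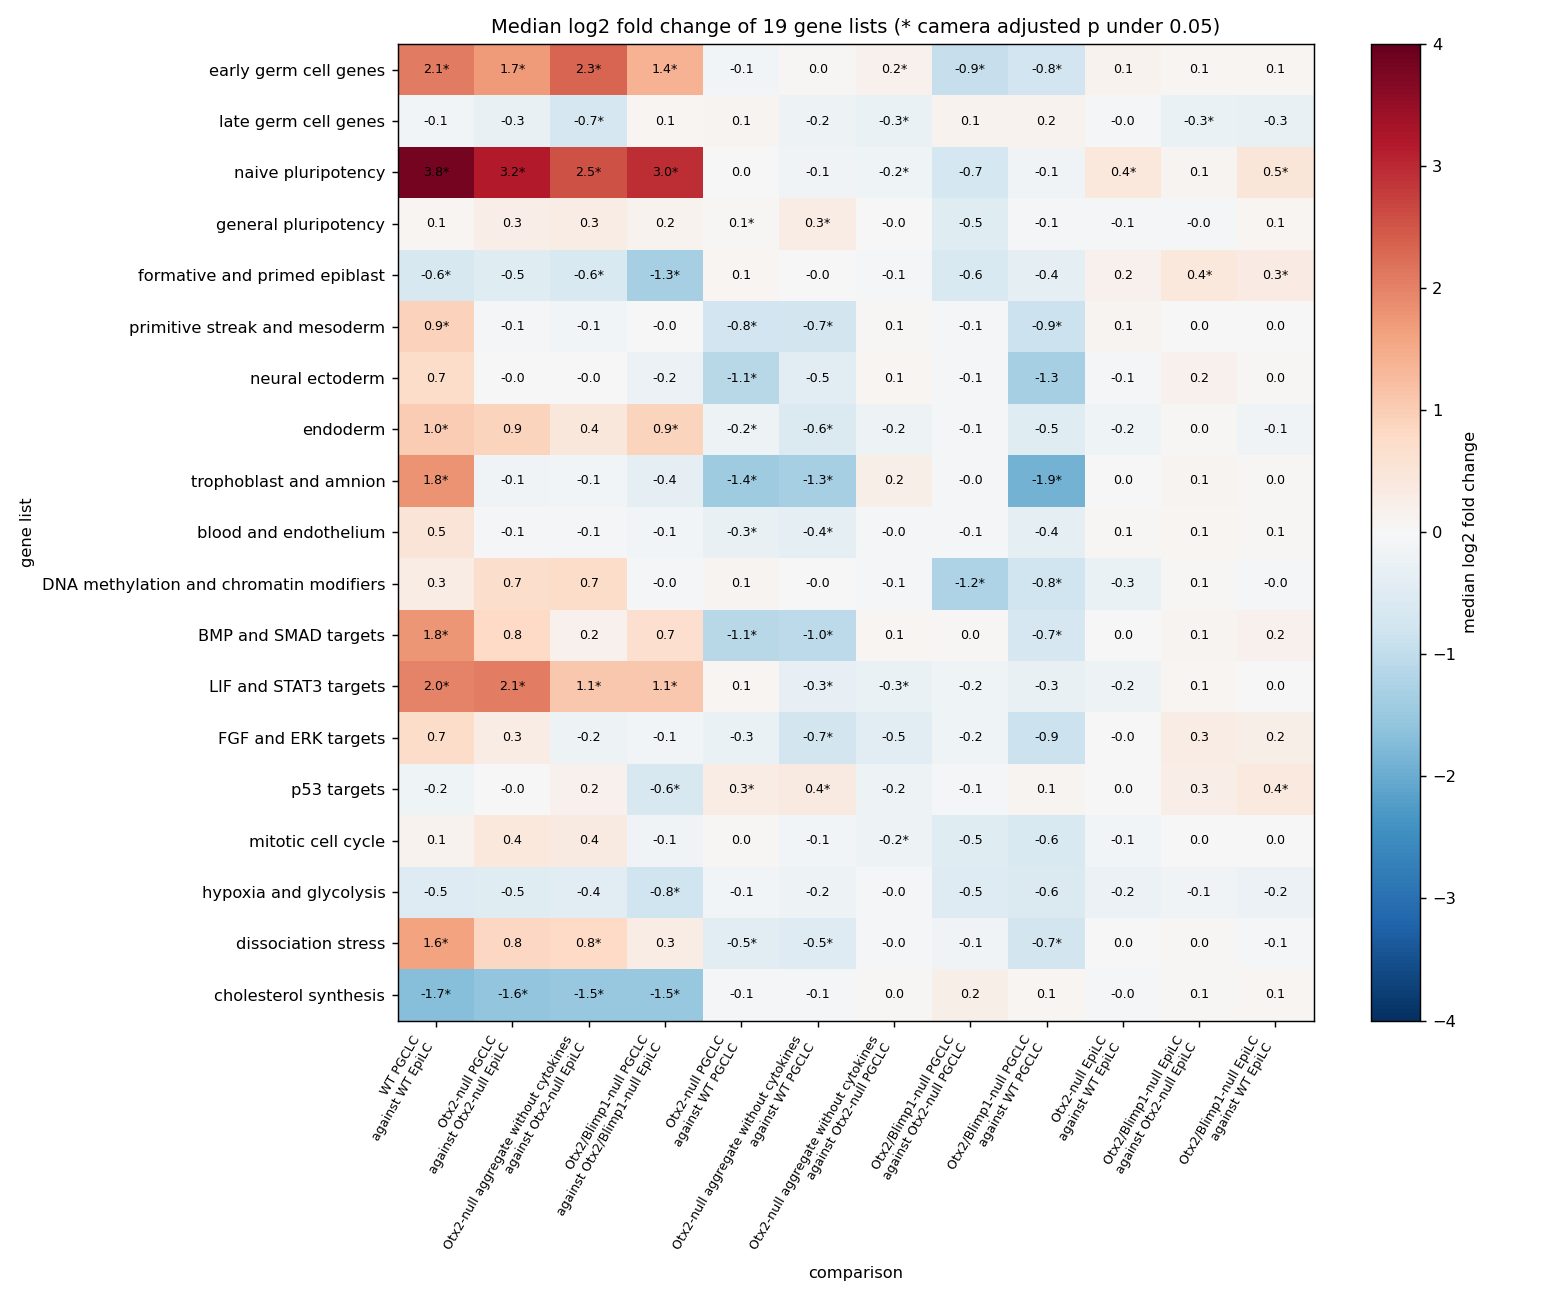
Median log2 fold change of the 19 fixed gene lists, as rows, in the 12 comparisons, as columns, on a colour scale from -4 to 4. Of the 228 list and comparison pairs, the 67 past camera adjusted p of 0.05 carry an asterisk, and naive pluripotency in WT has the largest median, 3.83.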

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

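The contrasts between induction changes were planned, while the tests of explanations for them, the splits of the arrays and the look at probes without a gene name were chosen after the results were seen.

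The change from EpiLC to day 6 differed between lines in a direct test. Between Otx2-null and WT cells it differed for 1916 genes, and between Otx2/Blimp1-null and Otx2-null cells for 5686. Of 100 ways to exchange arrays between lines within a stage, only the real one gave a count as large for either contrast. The highest other counts, 1382 and 4978, still hold much of the difference, so chance is not excluded.

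Among the lists, the Otx2-null change was lower than that of WT for primitive streak and mesoderm (median -1.15), trophoblast and amnion (-1.56), BMP and SMAD targets (-0.72) and blood and endothelium (-0.50). With an estimated correlation the last 2 did not pass (adjusted p = 0.0527 and 0.0596). The Otx2/Blimp1-null change was lower than the Otx2-null change for formative and primed epiblast (-0.95) and for DNA methylation and chromatin modifiers (-1.65), and neither passed with an estimated correlation (adjusted p = 0.481 for each).

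Among panel genes, the change was lower in Otx2-null than in WT cells, meaning a weaker rise or a stronger fall, for Klf2 (-3.89), Dppa3 (-3.59), Tfap2c (-2.54), Esrrb (-2.39), Dnd1 (-1.55), Id1 (-1.34), Nanos3 (-1.33), Nanog (-1.29) and Dnmt3b (-0.74). It was higher for Fgf5 (2.15) and Otx2 (1.61), which fell less, and Dazl (0.90). Fgf5 was detected on 1 array per PGCLC group, Klf2 on none in WT EpiLC and Nanos3 on no EpiLC array. Their values are not exact, with Klf2 at -3.46 and Nanos3 at -1.60 at the floor. The call for Dazl was lost in the model of only these groups (adjusted p = 0.0748), with array weights (0.0502), without background correction (0.0503), without a detection filter (0.0621) and without WT EpiLC replicate 2, WT PGCLC replicate 1 or 2, Otx2-null EpiLC replicate 3 or Otx2-null PGCLC replicate 2 or 3 (0.69 to 0.94). That for Dnmt3b was lost without background correction (adjusted p = 0.0569), without a detection filter (0.0528) and without any array but WT PGCLC replicate 1, Otx2-null EpiLC replicate 3 and Otx2-null PGCLC replicates 1 and 2 (-0.78 to -0.60). Other probes gave 0.14 for Esrrb, 0.22 for Nanog and -0.52 for Tfap2c, and the mean of probes -0.53 for Nanog, none past the test.

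Between Otx2/Blimp1-null and Otx2-null cells the change was lower for Tfap2c (-2.06), Dnmt3b (-1.93), Fgf5 (-1.60), Dppa3 (-1.57), Pou3f1 (-1.55), Esrrb (-1.49), Dnd1 (-1.41), Klf2 (-1.31), Kit (-1.30), Sox2 (-1.17), Nanos3 (-0.79) and Prdm14 (-0.61). It was higher for Dazl (1.42), Nanog (0.82), Otx2 (0.64) and Pou5f1 (0.50). Nanos3 and Prdm14 were not detected in either EpiLC, nor Fgf5 in Otx2/Blimp1-null PGCLC, so their values are not exact, and with the floor in place they were -0.62, -0.47 and -0.99. The call for Pou5f1 was lost in the model of only these groups (adjusted p = 0.0826), after the correction for gene span (0.131), without background correction (0.0508) and without any of the 12 arrays but Otx2-null EpiLC replicate 3 and Otx2/Blimp1-null EpiLC replicate 1 (0.33 to 0.53). That for Prdm14 was lost without background correction (adjusted p = 0.129), after the correction for gene span (0.0733) and without Otx2-null EpiLC or PGCLC replicates 1 or 3, Otx2/Blimp1-null EpiLC replicate 3 or Otx2/Blimp1-null PGCLC replicates 1 or 2 (-0.59 to -0.54). Without Otx2-null PGCLC replicate 1 the calls for Nanos3 (-0.55), Nanog (0.70) and Otx2 (0.52) were lost, without Otx2-null EpiLC replicate 3 that for Nanog (0.68), and without Otx2/Blimp1-null PGCLC replicate 1 that for Nanos3 (-0.67). Other probes gave 0.047 for Esrrb, 0.56 for Sox2, 0.54 for Nanog and -0.67 for Kit, the mean of probes gave -0.31 for Sox2 and 0.68 for Nanog, and the authors' normalized table gave -0.40 for Nanos3, none past the test.

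Mesoderm and trophoblast genes were the first pattern weighed, and of 27 measured, 18 were lower in Otx2-null than in WT PGCLC, by a median of -1.76. A line difference already in EpiLC is argued against as the whole cause for the 5 of them detected on all WT EpiLC arrays. Their EpiLC differences, not used to pick them, ran from -1.13 to 1.31, and all 5 changes were lower (median -2.48). For the other 13 it cannot be told apart, as 10 were detected on no WT EpiLC array. Of all 18, 3 were lower in EpiLC and 17 had a lower change, which picking them at day 6 favours. For fibroblasts or smooth muscle cells in the WT sort, only a large share is argued against. In WT PGCLC, 12 genes abundant in them but not detected on all WT EpiLC arrays had a median signal of 4.95 (upper quartile 5.26). The lineage genes had 6.88. A small share stays open. Stromal genes (5 of 12 lower, median -0.44) and Acta2 (-6.41) were lower in Otx2-null PGCLC, but also in EpiLC (-0.41 and -4.94). Mesoderm-like or trophoblast-like cells in the WT sort cannot be told apart from an effect of Otx2, because the median of early germ cell genes, -0.117, would hide a small share, and the genotype itself was not tested apart from its line.

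The smaller share of WT induction in Otx2/Blimp1-null cells was the second pattern weighed. Remaining EpiLC-like cells are argued against as the whole cause, since of 76 genes at least 8-fold lower in Otx2-null PGCLC than EpiLC, 50% kept under 10% of their EpiLC signal and 14.5% kept over 50%. A trend with gene span (Spearman r = -0.265 against Otx2-null, -0.218 against WT PGCLC) is argued against for the gap between the shares. The gap was 39.9 points after its removal and 40.1 before. Fewer detected probes cannot be judged, since the shares were not recomputed for the 6606 genes detected on every array of the 4 groups. Of these, 4378 had a differing change. Loss of Blimp1 and other differences of this line stay open and may act together, since each genotype was 1 line.

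Outside the tested genes, 1755 of 3491 detected probes without a gene name changed between WT EpiLC and WT PGCLC, a signal not used above.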

How the results depend on the processing

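The lists, the main model, the gene rule and all alternatives below were fixed before the data were examined, except the correction for a trend with gene span, the restriction to genes detected on all arrays compared, and the splits, which were chosen after the results were seen. For the 14 counts of changed genes, the 3 overlaps with WT induction and the total of shifted lists, the range counted as unchanged was 1.5-fold either way. All that were run stayed within it with log2 of the signal plus a constant, an offset of 50, no detection filter, detection p under 0.01, the mean of a gene's probes and the correction for gene span. With the replicate number as a block every count also stayed within it (2257 for Otx2-null against WT EpiLC, and 67 lists), so treating the numbers as a pairing changed no count by that much.

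Other alternatives moved counts. With each probe tested on its own, more probes than genes are tested, and counts were 12491 for WT PGCLC against EpiLC, 13337, 13442 and 8477 for the inductions of Otx2-null cells, of those without cytokines and of Otx2/Blimp1-null cells, 3958 and 4585 for Otx2-null PGCLC and cytokine-free cells against WT PGCLC, and 9388 and 11084 for Otx2/Blimp1-null against Otx2-null and WT PGCLC. In EpiLC they were 3330 for Otx2-null against WT, 2862 for Otx2/Blimp1-null against Otx2-null and 3199 against WT, for the contrasts of changes 2959 and 9372, and for the overlaps 9951, 9810 and 4949. A change of at least 2-fold, a stricter demand by construction, left 4022, 4198, 4379 and 1935 for the inductions, 642, 764 and 476 for Otx2-null PGCLC against WT, cytokine-free cells against WT and cytokine-free against cytokine-treated cells, and 2065 and 3009 for Otx2/Blimp1-null against Otx2-null and WT PGCLC. In EpiLC it left 566, 134 and 507, for the contrasts of changes 1025 and 3504, and for the overlaps 3066, 3043 and 1038.

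Array weights gave 3753 for Otx2-null and 4418 for cytokine-free cells against WT PGCLC and 1068 for Otx2/Blimp1-null against Otx2-null EpiLC, and the cause was not tested. With only the groups compared in the model, fewer arrays estimate the spread, and 1049 genes passed for Otx2-null against WT EpiLC and 36 for Otx2/Blimp1-null against Otx2-null EpiLC. Among genes detected on all arrays compared, of which there are fewer, the contrast of Otx2-null and WT changes gave 1197. The authors' normalized table gave an overlap of 1911 for Otx2/Blimp1-null PGCLC, and the cause was not tested. Of 67 shifted lists, 48 stayed past the test without genes shared between lists, 53 in the authors' normalized table and 24 with an estimated correlation, and fry, which asks another question, called 141.

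Leaving out 1 array at a time, the count for Otx2/Blimp1-null against Otx2-null EpiLC ran from 598 (without Otx2/Blimp1-null EpiLC replicate 1) to 1844, with 1167 without Otx2-null EpiLC replicate 3. The other 13 counts and the overlaps stayed within 1.5-fold. Of 1914 values of named genes with 1 array left out, 1830 kept sign and side of the threshold, 71 lost the call, 2 gained it and none that was called changed sign.

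For values past the test in either setting, signs turned only where probes of a gene were treated in another way, and the cause was not tested. Values not past the test in either setting also turned, 11 with 1 array left out, 4 with array weights, 3 with the mean of probes, 2 on single probes, and 1 each without background correction and with the correction for gene span. On a second probe Nanog gave 1.51, 1.13 and 1.73 for Otx2-null PGCLC, cytokine-free cells and Otx2/Blimp1-null PGCLC against WT PGCLC, and the mean of its probes gave 0.28 and 0.78 for the last 2. The second probe of Kit gave 0.42 and 0.57 for Otx2-null PGCLC and cytokine-free cells against WT PGCLC and 0.085 for Otx2-null against WT EpiLC. That of Sox2 gave -0.14 for Otx2-null against WT PGCLC and 0.15 for Otx2/Blimp1-null against Otx2-null PGCLC, and that of Tfap2c gave -0.18 for Otx2-null against WT EpiLC. For the contrast of Otx2-null and WT changes, second probes gave 0.14 for Esrrb and 0.22 for Nanog, and for that of Otx2/Blimp1-null and Otx2-null changes 0.047 for Esrrb and 0.56 for Sox2. Of 4448 genes with several kept probes, 323 had probes called in opposite directions between WT EpiLC and PGCLC.

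Among 291 values of named genes, 19 calls ended in the authors' normalized table, against 9 without background correction and 9 with only the groups compared. Signal over background limits such values, since signals under about 100 units lie near the floor of that table. With detection p under 0.01 the genes left had medians of 0.16, 0.16 and 0.15 in the inductions of WT, Otx2-null and cytokine-free cells, against 0.058, 0.047 and 0.034 for all genes. The correction for gene span also centres the values, and it moved the share of higher genes among those called from between 39.7% and 61.2% to between 46.8% and 52.4%, so the balance of higher and lower counts is not read.

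For every comparison of 2 groups, every overlap and the lists, 3 arrays against 3 give 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 7320 and 1 for the WT induction, 7628 and 0 for Otx2-null, 7687 and 0 without cytokines and 5038 and 0 for Otx2/Blimp1-null cells. They were 2481 and 1, 2841 and 1, 1820 and 3, 5625 and 0, and 6602 and 0 at day 6 in the order above. In EpiLC they were 2183 and 16, 1864 and 6, and 2112 and 0. Overlaps were 5902, 5853 and 2965 against 0, and lists 67 against 47, so wrong labels also give list calls. For Otx2-null against WT EpiLC, whose numbers pair, other splits parting all 3 pairs gave at most 1 gene.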

Other observations

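All gene lists and tests in this part were chosen after the results were seen, so their p-values describe the genes chosen. Igf2 and Dlk1 prompted the imprinted lists and Zscan4c that of the 2-cell embryo, and for these no p is given. Of 10 paternally expressed imprinted genes measured, 7 rose and none fell from WT EpiLC to WT PGCLC (median 1.37). In Otx2-null PGCLC 6 were lower than in WT PGCLC and none higher (median -1.24), and the difference between the changes was -1.24. Mesoderm (-0.76), trophoblast (-1.41) and stromal genes (-0.44) were also lower there in Otx2-null PGCLC. Against WT PGCLC, cytokine-free cells had 5 lower and 1 higher (median -0.60) and Otx2/Blimp1-null PGCLC 7 lower and 1 higher (median -1.25). The mean log2 signal of Igf2 was 14.2 in WT PGCLC, 8.06 in Otx2-null PGCLC, 10.4 without cytokines and 8.13 in Otx2/Blimp1-null PGCLC. Maternally expressed imprinted genes, of which 5 were measured, had a median of -0.63 between Otx2-null and WT PGCLC, with 1 higher and 2 lower.

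Replication-dependent histone genes fell during induction in WT cells, with 39 of 51 lower and 2 higher (median -1.93, adjusted p = 2.9e-13, or 0.0585 with an estimated correlation), and in Otx2-null cells with 39 lower (-1.74, adjusted p = 2.34e-11, or 0.177 estimated). In Otx2/Blimp1-null cells 18 fell (-0.14, adjusted p = 0.113), and the difference from the Otx2-null change was 1.26 (40 higher, adjusted p = 2.5e-13, or 0.107 estimated). Genes of oxidative phosphorylation subunits, 69 in number, had medians of -0.53 in WT, -0.60 in Otx2-null and 0.23 in Otx2/Blimp1-null cells (adjusted p = 2.2e-05, 3.12e-05 and 0.00419, or 0.23, 0.343 and 0.493 estimated), with a difference of 0.79 between the last 2 changes (adjusted p = 1.19e-11, or 0.107 estimated). Ribosomal protein genes had a median of -0.11 in WT (adjusted p = 0.0643). Between Otx2/Blimp1-null and WT PGCLC, 40 histone genes were higher (1.11, adjusted p = 4.42e-13, or 0.0405 estimated), and 18 of 49 ribosomal genes were higher and 2 lower (0.18, adjusted p = 0.00364, or 0.0405 estimated). Histone genes are short, and whether the trend with gene span or polyadenylation of their transcripts accounts for these values was not tested.

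Genes of the 2-cell embryo gave the last pattern weighed. Of Zscan4c, Tcstv1, Tcstv3, Tmem92 and Arg2, all 5 were lower in Otx2-null cells without cytokines than with them (median -3.48), and the mean of Zscan4c was 5.56 against 11.2. Signal shared between Zscan4 copies is argued against as the whole cause, since the 4 other members had a median of -3.36. ES-like cells in the cytokine-treated sort cannot be told apart from an effect of the cytokines within the cells, because the median of naive genes, -0.18, would hide a small share of such cells. A hypothesis is that the cytokines may raise a small 2-cell-like fraction, and the arrays do not test it.

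Genes abundant in stromal cells, 12 of which were measured, had a median of -0.44 between Otx2-null and WT PGCLC (adjusted p = 0.0027, or 0.0509 estimated) and of -0.41 between the EpiLC of these lines (adjusted p = 0.0224, or 0.263 estimated).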
